A study of Sorghum propinquum with 2 samples.

How the data were processed

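Total RNA of 1 rhizome sample and 1 shoot sample was sequenced as Illumina RNA libraries, per the labels' protocols, which name TRIzol for the extraction. The aligner, the counting program, the genome build, the annotation, any filter and whether strand was used are not given in the sources used here. Samples were grouped by the tissue label. Each deposited table lists the same 24371 locus IDs with a gene length in bases, a read count and an RPKM, per the file headers. The deposited counts are whole numbers of reads per gene, and each listed gene has at least 1 read in one of the libraries. The deposited RPKM values of the authors (reads per 1000 bases of gene and per 1000000 reads) were recomputed from the counts and lengths and differed by less than 0.0001, with the total of the count column as the number of reads. Reads outside the listed genes therefore do not enter the scaling. The lengths run from 124 to 89248 bases with a median of 2369, and how the authors measured them is not stated, so RPKM levels depend on that choice while the ratio of a gene between the libraries does not. Genes that overlap, antisense genes and near-identical copies can share reads in ways that these tables do not show.

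The depth was 16862624 reads in genes for the rhizome library and 17153968 for the shoot library, with a median of 167 and 177 reads per listed gene. With 1 library per organ, a count model has no residual degrees of freedom, so edgeR's quasi-likelihood test was not used and genes were called by a fixed size: at least 4-fold and at least 5 RPKM in the higher library. Ratios of the 2 counts, scaled by the library totals, have exact conditional binomial (Clopper-Pearson) 95% intervals, as have shares of reads. The intervals cover counting error only. Detection was set at 1 RPKM, and the log2 ratios that rank genes used a pseudocount of 1 RPKM. These rules, the alternatives and the named-gene rule were fixed before the data were examined.

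The named-gene rule takes the genes with the largest log2((rhizome + 1)/(shoot + 1)) in each direction among genes past the size rule, and limits them to 2 IDs per direction where nothing pairs IDs with names. That limit applied. For the same reason the 28 gene lists fixed in advance as patterns on product names (pathways, hormones, tissue markers and others) could not be filled, so 0 lists were tested, including those for green, root, dividing and vascular tissue. The rule also asked for the 5 most abundant genes per library, of which the leading ones are described without IDs.

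Alternatives were fold thresholds of 2 and 8, minimums of 1 and 20 RPKM, ratios with a pseudocount, a median-of-ratios scaling, TMM scaling (edgeR 4.0.16 in R 4.3.3, trims of 30% and 5%), scaling without the 100 most abundant genes of either library, and calls whose interval lay wholly beyond 4-fold. A minimum of 5 CPM (reads per 1000000 reads of the library) and a minimum length of 500 bases were added after seeing the data. Chromosome numbers were read from the IDs (the 2 digits after "Sb"), which 24215 of the IDs carry and 156 do not. The sources used here do not say which species' genome these IDs describe. Chromosome, gene length and ID order may therefore differ in *Sorghum propinquum*. Chromosome shares were set beside 10000 random gene sets matched on expression and beside 10000 shuffles of blocks of 20 consecutive genes, and neighbours in ID order beside 1000 shuffles within chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

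The code was tested on simulated data: Poisson counts for the 24371 genes at the mean levels and totals of the rhizome and shoot libraries, with 200 genes of at least 10 RPKM changed. The rule called 0 of 50 genes changed 2-fold, 49 of 50 changed 6-fold, 50 of 50 changed 10-fold, 50 of 50 changed 16-fold and 0 of 24171 unchanged genes. The intervals held the true ratio for 96.2% of genes. The simulation has no variation between plants, so it tests the arithmetic and not the organs.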

Results

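RNA sequencing was compared between 2 organs of *Sorghum propinquum*, a wild sorghum relative that spreads by rhizomes, which are stems that grow underground. The series asked how the transcriptome of the rhizome differs from that of the shoot. Both organs came from 1 greenhouse-grown vegetative clone at the active tillering stage, when the plant forms side shoots. There was 1 library per organ, so no value below has an error between samples and no p-value across genes is given. The intervals are exact 95% intervals that cover counting error only. The labels mention no molecular identifiers, so reads may not be independent molecules. The rhizome library held 16862624 reads in genes and the shoot library 17153968, which is 1.73% more. A count of 0 allowed up to 3 reads, or 0.178 CPM in the rhizome library and 0.175 CPM in the shoot library. The deposited tables identify genes by locus ID and give no gene names, positions or products, so genes are described here as groups, and 4 are named by ID.

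Most expressed genes were shared by the rhizome and the shoot. At a minimum of 1 RPKM, 17801 genes were detected in the rhizome library and 18233 in the shoot library. Both libraries detected 16710 genes, 86.5% of the 19324 detected in either. A further 1091 genes reached 1 RPKM in the rhizome library alone and 1523 in the shoot library alone. Across these 19324 genes, the 2 libraries correlated with Pearson's r = 0.81 on the log2(RPKM + 1) scale and Spearman's rho = 0.79. Genes are not independent replicates, so these coefficients describe this pair of libraries.

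Large differences were mostly in favour of the shoot. Among the 12826 genes with at least 5 RPKM in either library, 1157 genes (9.02%) were at least 4-fold higher in the shoot library, and 231 genes (1.80%) were at least 4-fold higher in the rhizome library. These groups are called shoot-higher and rhizome-higher genes. The shoot-higher group was 5.01 times the size of the rhizome-higher group. The counting interval of the ratio lay wholly beyond 4-fold for 949 of the shoot-higher genes (82.0%) and 149 of the rhizome-higher genes (64.5%), and it included a ratio of 1 for 0 genes of either group. The intervals compare the reads of these 2 libraries, not the organs in general.

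**Figure D1:**
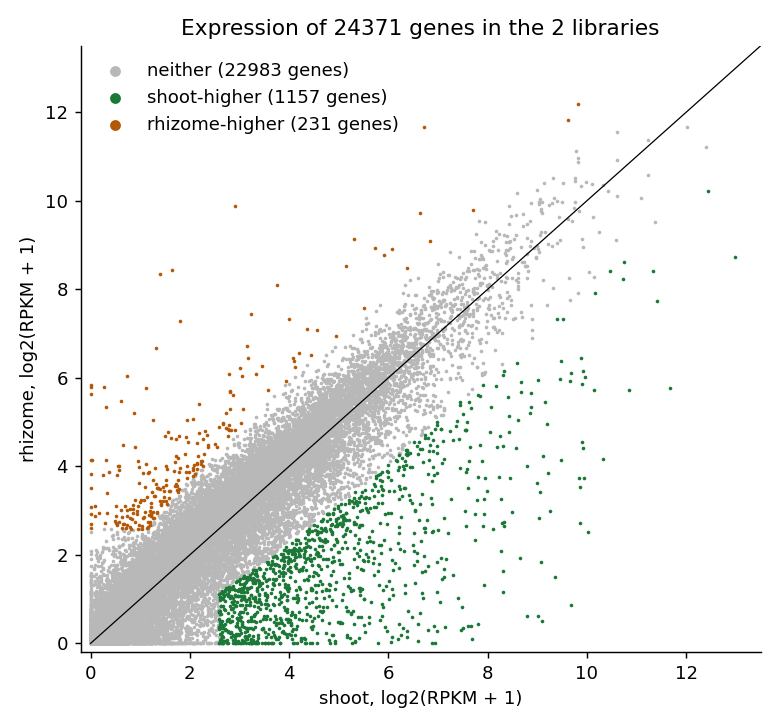
Expression of each listed gene in the rhizome library (vertical axis) against the shoot library (horizontal axis), both as log2(RPKM + 1), with 1 point per gene and the line of equal values in black. The 1157 shoot-higher genes extend further from the line, and at higher expression, than the 231 rhizome-higher genes.

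Small differences ran the other way in the values as deposited. Of the 16710 genes at 1 RPKM or more in both libraries, 61.6% had a higher RPKM in the rhizome library, a share that is 50% by construction under median-of-ratios scaling and was 52.7% under TMM scaling and 60.8% under scaling without the 100 most abundant genes of either library. Their median log2 ratio of rhizome to shoot, taken without a pseudocount, was 0.22, a 1.17-fold difference, with quartiles of -0.35 and 0.63. Among the 12826 genes with at least 5 RPKM in either library, 6203 were higher in the rhizome by less than 2-fold and 3055 were higher in the shoot by less than 2-fold. The 2- to 4-fold class held 1181 genes higher in the rhizome and 999 higher in the shoot. This order flipped to 634 and 1239 under median-of-ratios scaling and to 718 and 1157 under TMM scaling. It did not flip without the 100 most abundant genes, at 1119 and 1018. The order of the class under 2-fold did not flip, at 5093 and 3916 under median-of-ratios scaling and 5386 and 3742 under TMM scaling. Fewer genes reached 5 RPKM in either library under these 2 scalings, 12368 and 12473. In the values as deposited, the class of 16-fold or more held 43 genes higher in the rhizome and 449 higher in the shoot. Median-of-ratios scaling, which sets the median ratio of the shared genes to 1, lowers every log2 ratio of rhizome to shoot taken without a pseudocount by the same 0.22. With it, 166 genes were rhizome-higher and 1320 shoot-higher, and the class of 16-fold or more held 38 and 496.

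**Figure D2:**
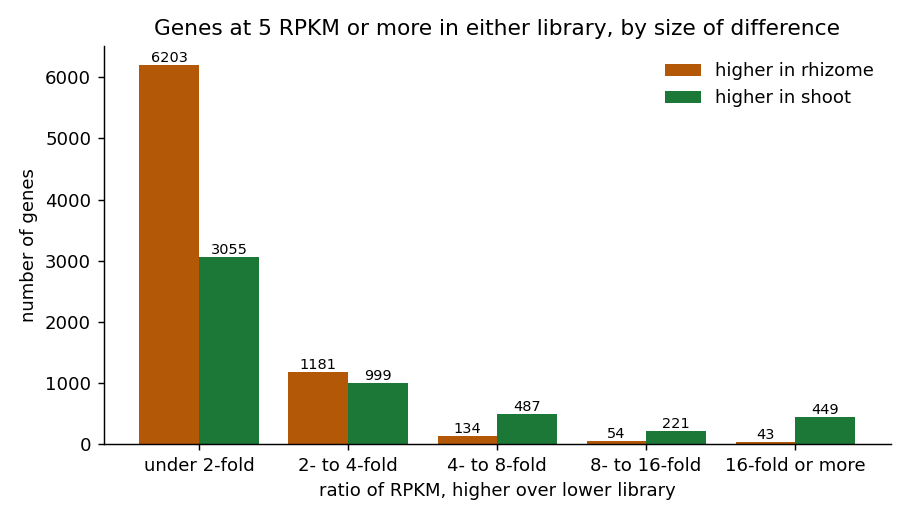
Number of genes (vertical axis, from 0) by the ratio of RPKM between the higher and the lower library (horizontal axis), for genes at 5 RPKM or more in either library, with bars for genes higher in the rhizome and genes higher in the shoot. Rhizome bars are taller up to 4-fold in the values as deposited (1181 against 999 genes at 2- to 4-fold, which flips to 634 against 1239 under median-of-ratios scaling and to 718 against 1157 under TMM scaling), and shoot bars are taller beyond it (449 against 43 genes at 16-fold or more).

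The shoot-higher genes made up a sizeable part of the shoot transcriptome. They took 13.2% of the shoot reads (interval 13.19% to 13.23%) and 1.24% of the rhizome reads (1.238% to 1.248%). The rhizome-higher genes took 3.17% of the rhizome reads (3.159% to 3.176%) and 0.453% of the shoot reads (0.450% to 0.456%). Both groups were chosen by their ratio, so a gap of at least 4-fold between the libraries follows from the choice. Shoot-higher genes had a median of 19.99 RPKM and 594 reads in the shoot library, and rhizome-higher genes a median of 14.1 RPKM and 318 reads in the rhizome library. At 100 RPKM or more in their own library there were 182 shoot-higher and 25 rhizome-higher genes. Of the 148 genes whose higher value was 500 RPKM or more, 44 (29.7%) were shoot-higher and 8 (5.41%) rhizome-higher, against 7.91% and 2.08% of the 3997 genes at 5 to 10 RPKM. At 10 to 50, 50 to 100 and 100 to 500 RPKM, 7.92%, 11.1% and 16.8% were shoot-higher. The rhizome-higher shares there were 1.54%, 1.74% and 2.07%, not above that at 5 to 10 RPKM. Classes were set by the higher of the 2 values, so a large difference can itself lift a gene into a higher class. Deposited length, which enters RPKM, was not matched between the classes.

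The most abundant transcripts differed in part between the 2 libraries. Of the 100 genes with the most reads in each library, 55 were in both lists. In the rhizome list 10 genes were rhizome-higher and 0 shoot-higher. In the shoot list 25 genes were shoot-higher and 2 rhizome-higher. The gene with the most reads in the rhizome library had 4635 RPKM there and 909 RPKM in the shoot, a 5.10-fold difference. The gene with the most reads in the shoot library had 2737 RPKM there and 211 RPKM in the rhizome, a 13.0-fold difference. The gene with the highest RPKM in the shoot library, listed at 475 bases, had 8149 RPKM there and 421 RPKM in the rhizome. The single most abundant gene took 0.553% of the rhizome reads and 0.942% of the shoot reads, the 10 most abundant took 3.59% and 4.15%, and the 100 most abundant took 14.2% and 14.5%.

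The 2 genes with the largest ratios on the log2(RPKM + 1) scale in each direction were abundant in one organ and had 2 to 65 reads in the other. Genes without reads in the other library have no finite plain ratio and can rank lower on this scale. Sb03g006880 had 948 RPKM (7304 reads) in the rhizome library and 6.51 RPKM (51 reads) in the shoot library, which was 146-fold higher in the rhizome (interval 111 to 196). Sb06g000660 had 325 RPKM (12642 reads) in the rhizome and 1.64 RPKM (65 reads) in the shoot, which was 198-fold higher in the rhizome (155 to 257). Sb07g000600 had 825 RPKM (6172 reads) in the shoot and 0.816 RPKM (6 reads) in the rhizome, which was 1011-fold higher in the shoot (464 to 2757). Sb06g000790 had 546 RPKM (2621 reads) in the shoot and 0.424 RPKM (2 reads) in the rhizome, which was 1288-fold higher in the shoot (356 to 10643). On the log2(RPKM + 1) scale, which ranked them and understates the change of low values, the 4 ratios of rhizome to shoot were 6.98, 6.95, -8.83 and -8.59 in the same order.

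Genes with reads in 1 organ alone were mostly at the limit of detection. The rhizome library listed 1291 genes at 0 reads, and their median in the shoot library was 3 reads. The shoot library listed 732 genes at 0 reads, and their median in the rhizome library was 2 reads. For 1008 and 663 of these genes, respectively, the other library had 10 reads or fewer. The counting interval included a ratio of 1 at 5 reads against 0 and excluded it at 6, so a difference was hard to detect at the lowest of these counts. At 5 RPKM or more in the other library there were 51 genes at 0 in the rhizome and 10 genes at 0 in the shoot. Among the genes at 0 in the rhizome library, the most abundant had 4451 reads in the shoot library. Among those at 0 in the shoot library, the most abundant had 1224 reads in the rhizome library.

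Genes past the 4-fold rule had short deposited lengths, which may be genomic spans with introns, since how they were measured is not stated. The median deposited gene length was 1239 bases for rhizome-higher genes, 1435 bases for shoot-higher genes and 2526 bases for all genes at 5 RPKM or more in either library. The listed genes were divided into classes of 20% by length, and shares were taken over the genes of a class with at least 5 RPKM in either library. In the shortest class (124 to 1084 bases), 17.5% of 2346 such genes were shoot-higher and 4.13% rhizome-higher. In the longest class (4381 to 89248 bases), 3.02% of 2582 such genes were shoot-higher and 0.310% rhizome-higher. Both shares declined from each length class of 20% to the next longer one.

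**Figure D3:**
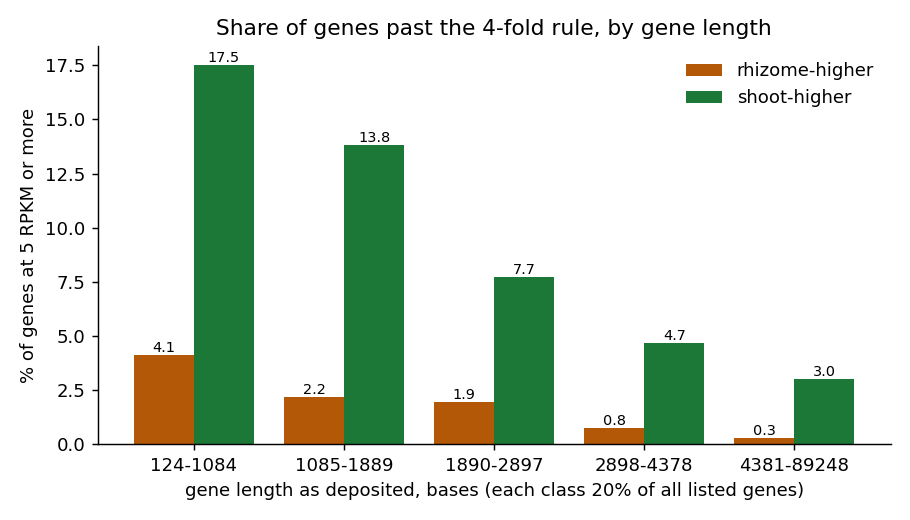
Share of genes at 5 RPKM or more that were rhizome-higher or shoot-higher (vertical axis, percent, from 0) in classes of deposited gene length in bases, each with 20% of the listed genes (horizontal axis). The shoot-higher share goes from 17.5% in the shortest class to 3.02% in the longest, and the rhizome-higher share from 4.13% to 0.310%.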

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

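The excess of shoot-higher over rhizome-higher genes held under each of the 11 alternatives, from 1.53 times at a 2-fold threshold to 7.95 times under median-of-ratios scaling, with the 3 rescalings lowering the rhizome values and so raising it. The rhizome-higher and shoot-higher counts were 1412 and 2156 at 2-fold, 97 and 670 at 8-fold, 528 and 1787 with a minimum of 1 RPKM, and 86 and 578 with a minimum of 20 RPKM. With the counting interval wholly beyond 4-fold they were 149 and 949. The remaining 6 alternatives, 2 of them added after seeing the data (5 CPM, 500 bases), gave 158 to 279 and 961 to 1320. With a minimum of 5 RPKM, 11154 genes were detected in the rhizome, 11188 in the shoot and 9516 in both. Pearson's r was 0.75 with a pseudocount of 0.1 and 0.87 over all listed genes, where rho was 0.87. The 4 named IDs kept their direction in 16 of 16 values, with absolute log2 ratios of 5.63 to 10.03. They were chosen for their extreme ratios, which these alternatives could not reverse, so this does not test their direction. Of the 16 values, 7, all from another pseudocount, left the interval that the exact Poisson limits of the 2 counts give on the log2(RPKM + 1) scale. Alternatives for the gene lists were not run, since no list could be filled. No paired analysis was possible because each organ has 1 library. Nothing could be left out in turn for the same reason, so variation between plants stays unknown.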

Other observations

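Chromosomes, gene length and ID order were examined after the data were seen, and of the tests below, those on rhizome RNA in the shoot library, on chance order and on overlapping neighbours were chosen after the result was seen. Chromosome 5, by the number in the ID, had the highest share of shoot-higher genes of the 10 chromosomes. There, 72 of 553 genes at 5 RPKM or more were shoot-higher, or 13.0% (exact 95% binomial interval over genes 10.3% to 16.1%). Unlike the intervals above, this one covers no read-counting error and treats genes as independent. Random gene sets matched on expression averaged 9.30%, and the observed share lay at their 99.88th percentile. With gene length matched as well, it lay at the 99.97th percentile. Since neighbouring genes resemble each other, blocks of 20 consecutive genes were also shuffled, and it lay at the 99.89th percentile. Chromosome 10 had the lowest share, 7.15% of 1021 genes, at the 1.48th percentile, or the 1.66th among shuffled blocks, and the other 8 chromosomes lay between the 7.91th and 71.1th percentiles. Rhizome-higher genes had their highest share on chromosome 6, 2.43% of 1154 genes, at the 94th percentile, and their lowest on chromosome 9, 1.19% of 1088 genes, at the 3.66th percentile. The percentiles describe this pair of libraries, and 40 were computed.

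The shoot-higher group outnumbered the rhizome-higher group 5.01-fold although the median gene was slightly higher in the rhizome in the values as deposited. Library scaling set by abundant shoot genes lowers the other shoot values, which works against a shoot-higher excess. Rescaling for it could only raise the ratio of the group sizes, so it does not test this explanation. The 3 rescalings lowered the rhizome values and gave 5.21 at the lowest, so none removed the excess. Counting noise in genes with few reads is argued against as the source of the excess, since 949 shoot-higher and 149 rhizome-higher genes had a counting interval wholly beyond 4-fold. Their ratio was 6.37. The rise from 5.01 came from this filter keeping 82.0% of the shoot-higher and 64.5% of the rhizome-higher genes. Rhizome RNA in the shoot library could hide rhizome-higher genes, but 4 of the 8246 genes with 400 rhizome reads or more had 0 shoot reads, which allows at most 1.53% of it at 95% confidence, for counting error alone and if it brings all rhizome transcripts alike. A difference between the organs stays open and untested, as do the make-up of each sample in cell types and any difference between these 2 samples that is unrelated to the organ.

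Genes of short deposited length passed the 4-fold rule more often, with 21.7% of the 2346 genes at 5 RPKM or more in the shortest length class and 3.33% of the 2582 such genes in the longest class past it in either direction, a 6.50-fold difference. A minimum in RPKM, which favours short genes, is argued against as the whole cause, since with a minimum of 5 CPM the shortest class still had 5.43 times the share of the longest. Counting noise of short genes is argued against as well. The genes with at least 100 reads in the higher library numbered 1794 in the shortest class and 2582 in the longest. Of these, 308 and 78 passed with an interval wholly beyond 4-fold, a share 5.68 times as high in the shortest class. Whether short genes belong to families with organ-restricted expression may be asked once the IDs have gene names, and no biological explanation was tested here.

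Genes next to each other in ID order had weakly similar ratios of rhizome to shoot. Neighbours were taken among 19203 of the 24215 genes with a chromosome number, so other genes can lie between them. The correlation across genes at a step of 1 was r = 0.098, against at most 0.027 in 1000 shuffles within chromosomes, which argues against chance order. At a step of 2 it was 0.037, against at most 0.028, and above the 0.0097 that the square of the first value gives. That square applies only if all next neighbours are equally alike, and overlap confined to some groups of genes could exceed it. The comparison therefore cannot decide whether reads shared by overlapping neighbours are the cause. Tandem copies of one gene are a candidate explanation. The 131 next-neighbour pairs called in the same direction had a median difference in log2 length of 0.65. That was below the lowest of 1000 draws of as many next-neighbour pairs (0.71) and of as many called genes apart from each other (0.76). As a fold of length it was 1.57, against a median of 2.09 in the draws of next-neighbour pairs, so the lengths were only loosely alike. Pairs within a run share genes, so the 131 pairs are not independent. Copies with truly similar expression and copies that share reads were not separated, since no sequences were used.

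Next neighbours were both shoot-higher in 117 pairs, against a mean of 69.0 and a highest of 95 in 1000 shuffles, and both rhizome-higher in 14 pairs, against 2.63 and 8. Neighbours called in opposite directions made 14 pairs, against a mean of 27.3. The longest run of consecutive shoot-higher genes had 6 members, on chromosome 2, and the longest rhizome-higher run had 3, on chromosome 5. Of the deposited gene lengths, 47.0% left a remainder of 1 when divided by 3, against 26.3% with no remainder and 26.6% with a remainder of 2.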
